A study of Oryza sativa with 2 samples.

How the data were processed

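RNA sequencing libraries were made from young rice panicles shorter than 2 cm, with 1 library of the line XD1B, the wild type, and 1 library of the lf2 mutant. The values were deposited by the authors as FPKM per gene, that is, fragments per kilobase of gene length and scaled to the fragment total of the library, in a table with 1 column per library. The unit is named per the file headers and file name. The aligner, the counting tool, the genome build, the annotation version and any filter are not given in the sources used here. The table lists 57446 genes, of which 55801 carry locus identifiers of the MSU type and 1004 are unnamed additional loci. A further 340 and 301 are gene models with identifiers that start with ChrUn and ChrSy. With 1 library per group there are no replicates, so no difference below has a replicate check and no p-value was computed.

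Depth was recovered from the values themselves. Every FPKM value is a whole number of fragments divided by a whole-base gene length and by the library total, so the smallest values fix the total. This gave 29111346 fragments for the wild type and 27373728 for lf2, a ratio of 1.06. The tolerance for a whole fragment number was 0.0002 fragments plus 3e-07 of that number. Within it, a length and a pair of whole fragment numbers were found for 100% of genes above 0 in either library. With a wrong total they were found for 21.9% of 2000 genes above 0 in both. Fragments per gene are lower bounds, because a common factor of both numbers cannot be seen. In simulated libraries of 4000 genes, 86.4% of genes above 0 in both were recovered exactly and 100% exactly or as a lower bound. The recovered fragments sum to 89.1% and 88.2% of the totals. Intervals of a ratio are exact Clopper-Pearson 95% intervals from these fragments and cover counting error only.

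The measure of difference was log2((lf2 FPKM + 1)/(XD1B FPKM + 1)), taken over the 22150 genes with FPKM of at least 1 in either library. The pseudocount of 1 understates the difference of low genes. A gene counted as higher or lower where this log2 ratio was at least 1 or at most -1, which is a rule of size and not a test. For each gene list the median over measured members was computed with an order-statistic interval of about 95% over members, and placed among 10000 random lists of the same size matched on mean expression in 20 bins. A list was called where that percentile lay under 2.5 or over 97.5, as a description of these libraries. The procedure was tested on simulated data for XD1B against lf2 with 22150 genes, of which 200 differed 3-fold. Of these, 86.0% passed the 2-fold rule, and 91.3% of those with FPKM of at least 5 did, while 14 unchanged genes passed through counting error.

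The 15 gene lists, the size rule, the alternatives and the rule for naming genes were fixed before the data were examined. That rule names up to 4 members per list with the largest absolute log2 ratio, every member past the 2-fold rule where there are 5 or fewer, and the genes OSH1, HB1 and MADS1. Outside the lists it allows at most 2 identifiers in each direction. The lists held 205 members by symbol and MSU locus. The reference gene table of assembly ASM3414082v1 holds no MSU identifiers and matched 0 of them by identifier, so each pair of symbol and locus was compared with it by chromosome and order along the chromosome. This left 146 members checked and 48 without an entry, which stayed in the lists but are not named in the text, and removed 11. Lists added after the first results kept checked members only. Lists by gene description were not run, since no description was at hand, and the locus of LF2 itself is not given in the sources used here, so its level is not reported.

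Alternatives were pseudocounts of 0.1 and 5, no filter and a filter at FPKM of at least 5, a rescaling to a median ratio of 1 over genes with FPKM of at least 5 in both libraries, a rescaling to a sum of 1000000, and random lists not matched on expression. Restricting lists to checked members, and using all 205 members, were added after the data had been seen, as were, for the added lists, the members without an entry and no filter. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used with random seed 1.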

Results

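Messenger RNA levels were compared between young panicles of the rice line XD1B and of lf2, a mutant of LATERAL FLORET 2, which the series describes as an SNF2-type chromatin remodelling factor acting on the axillary meristem of the spikelet. The spikelet is the unit of the grass inflorescence that bears the florets. A single panicle library of each genotype was measured, at a depth of 29111346 fragments for the wild type and 27373728 for lf2. FPKM of at least 1 was reached by 20010 genes in the wild type and 21112 in lf2. There are no replicates, so each difference is between 2 libraries, and the intervals given with ratios cover counting error only.

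All measured spikelet identity and lateral organ genes (10, most of them YABBY genes) were lower in the lf2 library. All cell cycle and DNA replication genes (14) were lower too, and all 9 measured heat shock and jasmonate or wounding genes were higher. The floral genes MADS7, MADS6 and MADS1 were lower and the hormone genes GH3-2 and CKX4 higher, within lists whose other members went both ways. DL, a YABBY gene of carpel and midrib identity, stood at FPKM 40.3 in the wild type and 11.4 in lf2, a ratio of 0.282 (0.249 to 0.320). TIFY11C, a JAZ-type repressor of jasmonate signalling, stood at 1.09 and 113, a ratio of 104 (74.5 to 149).

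Among 22150 genes, 3395 (15.3%) were at least 2-fold higher in lf2 and 1822 (8.23%) at least 2-fold lower. The counting interval excluded equal levels for 3366 and 1812 of them. At 4-fold the numbers were 1831 higher and 14 lower. Across genes, which are not independent replicates, Spearman's rho was 0.765 and Pearson's r of the log2 values 0.745. The median log2 ratio of all these genes was -0.31. Rescaling to a median ratio of 1 over genes at FPKM of at least 5 in both libraries brought it to 0.05 and turned the split into 4410 higher and 389 lower. List medians are therefore best read against their random lists.

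**Figure D1:**
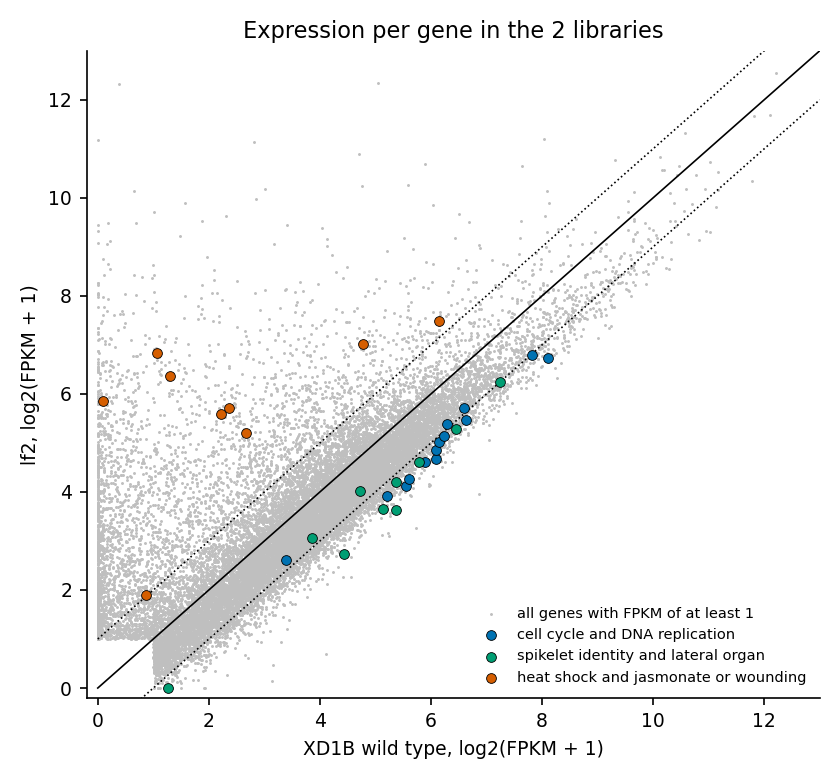
Expression of each gene with FPKM of at least 1 in either library, as log2(FPKM + 1), in the wild type (horizontal) and in lf2 (vertical); the solid line marks equal values and the dotted lines a 2-fold difference on this scale. Members of the cell cycle and spikelet lists lie under the solid line, and the 9 heat shock and jasmonate or wounding genes lie on the upper 2-fold line or above it.

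Spikelet identity and lateral organ genes had the lowest percentile of all lists together with the cell cycle genes. All 10 measured members were lower in lf2, 8 of them at least 2-fold, with a median log2 ratio of -1.18 (-1.70 to -0.80) at percentile 0 of the random lists. Besides DL, these included G1, which keeps sterile lemmas from becoming lemmas, at 20.5 and 5.63 FPKM, a ratio of 0.274 (0.224 to 0.334). The YABBY genes YAB2 and YAB4, expressed in lateral organs, had ratios of 0.339 (0.301 to 0.381) and 0.432 (0.391 to 0.478). Most measured members are YABBY genes, so the list median mainly follows that family. FZP was not measured, at 0.367 and 0.219 FPKM. The check by chromosome and order removed IDS1, MFS1 and REP1. After rescaling to a median ratio of 1, 4 members were at least 2-fold lower, and the median was -0.80, still at percentile 0. In the same lf2 library the heat shock and jasmonate or wounding genes were higher, with a median of 3.35.

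The floral MADS-box list was fixed beforehand and not split by function, so its median does not speak for floral organ genes alone. Of its 24 measured members, 8 were at least 2-fold lower and 2 at least 2-fold higher in lf2. Their median of -0.47 (-1.11 to 0.10) lay at percentile 22.8. MADS7, an E-class floral gene, stood at 72.6 and 21.6 FPKM, a ratio of 0.298 (0.247 to 0.357). The AGL6-type gene MADS6 stood at 83.3 and 27.3, a ratio of 0.327 (0.288 to 0.372). MADS1, which specifies lemma, palea and floret meristem, stood at 190 and 73.2, a ratio of 0.386 (0.369 to 0.404). MADS57 was higher in lf2, at 13.8 and 39.4, a ratio of 2.85 (2.57 to 3.16), as was MADS20, at 0.607 and 16.5, a ratio of 27.1 (16.97 to 46.2). After rescaling to a median ratio of 1, 3 members were at least 2-fold lower and 4 at least 2-fold higher.

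Of 9 measured meristem maintenance and KNOX genes, 1 was at least 2-fold lower and 0 at least 2-fold higher, with a median of -0.53 (-0.93 to -0.09) at percentile 17.5. OSH6, a KNOX gene, stood at 64.2 and 28.4 FPKM, a ratio of 0.441 (0.413 to 0.472). OSH15 stood at 134 and 76.3, a ratio of 0.568 (0.545 to 0.593). OSH1, which marks undifferentiated meristem cells, stood at 86.6 and 60.7, a ratio of 0.701 (0.672 to 0.732). LOG, which makes active cytokinin in meristems, was higher at 6.70 and 13.6, a ratio of 2.03 (1.76 to 2.33). After rescaling to a median ratio of 1 the split was 0 lower and 1 higher, and after rescaling to a sum of 1000000 it was 2 lower and 1 higher.

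All 5 class III HD-ZIP genes, which set the upper side of lateral organs, were lower in lf2, 1 of them at least 2-fold, and the median of -0.74 (-1.08 to -0.70) lay at percentile 19.6. HB1, the gene of this class altered in the related mutant lateral floret 1, stood at 101 and 61.7 FPKM, a ratio of 0.611 (0.590 to 0.633). HB3 stood at 133 and 71.2, a ratio of 0.534 (0.517 to 0.550). HOX29 was the member at least 2-fold lower, at 2.93 and 0.863, a ratio of 0.295 (0.212 to 0.404). With rescaling to a median ratio of 1, 0 of the 5 passed the 2-fold rule.

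Neither axillary meristem and panicle branching genes nor SNF2-family remodellers stood apart from random lists. Of 15 branching genes, 2 were at least 2-fold lower and 1 at least 2-fold higher, with a median of -0.33 (-0.75 to 0.06) at percentile 48.5. SPL13 stood at 280 and 143 FPKM, a ratio of 0.512 (0.496 to 0.529), and SPL16 at 13.03 and 7.68, a ratio of 0.589 (0.516 to 0.671). Of 12 SNF2-family genes, 1 was at least 2-fold lower, and the median of -0.31 (-0.80 to -0.15) lay at percentile 58.8. RAD54, a recombination gene, stood at 13.8 and 8.31, a ratio of 0.604 (0.553 to 0.659). Both medians change sign on rescaling to a median ratio of 1, to 0.06 and 0.07.

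Cell cycle and DNA replication genes were lower throughout. All 14 members were below the wild type, 11 of them at least 2-fold, with a median of -1.20 (-1.38 to -0.91) at percentile 0. The replicative helicase genes MCM6, MCM5 and MCM4 had ratios of 0.355 (0.333 to 0.377), 0.364 (0.345 to 0.384) and 0.386 (0.363 to 0.410). PCNA, the sliding clamp of DNA polymerase, stood at 275 and 105 FPKM, a ratio of 0.382 (0.367 to 0.397). After rescaling to a median ratio of 1, 2 members were at least 2-fold lower and the median was -0.82, again at percentile 0. Here too the heat shock and jasmonate or wounding genes moved with the genotype, with 9 of 9 higher in lf2.

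Meiosis and anther genes were fixed as markers of panicle stage. Among them C6, EAT1, PTC1 and TDR stayed under FPKM 1 in both libraries, so only part of the list could be read. All 14 measured members were lower in lf2, 3 of them at least 2-fold. Their median of -0.56 (-1.03 to -0.09) lay at percentile 4.01, inside the range not called. PAIR1, needed for homologue pairing, stood at 8.42 and 2.88 FPKM, a ratio of 0.342 (0.281 to 0.414). MEL1, a germ-cell Argonaute gene, stood at 29.05 and 13.7, a ratio of 0.473 (0.443 to 0.505). After rescaling to a median ratio of 1, 0 members were at least 2-fold lower and the interval of the median was -0.66 to 0.17. At FPKM of at least 5 the list is called, with a median of -0.92 over 7 members, and with all members as first fixed it lay at percentile 14.3.

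**Figure D2:**
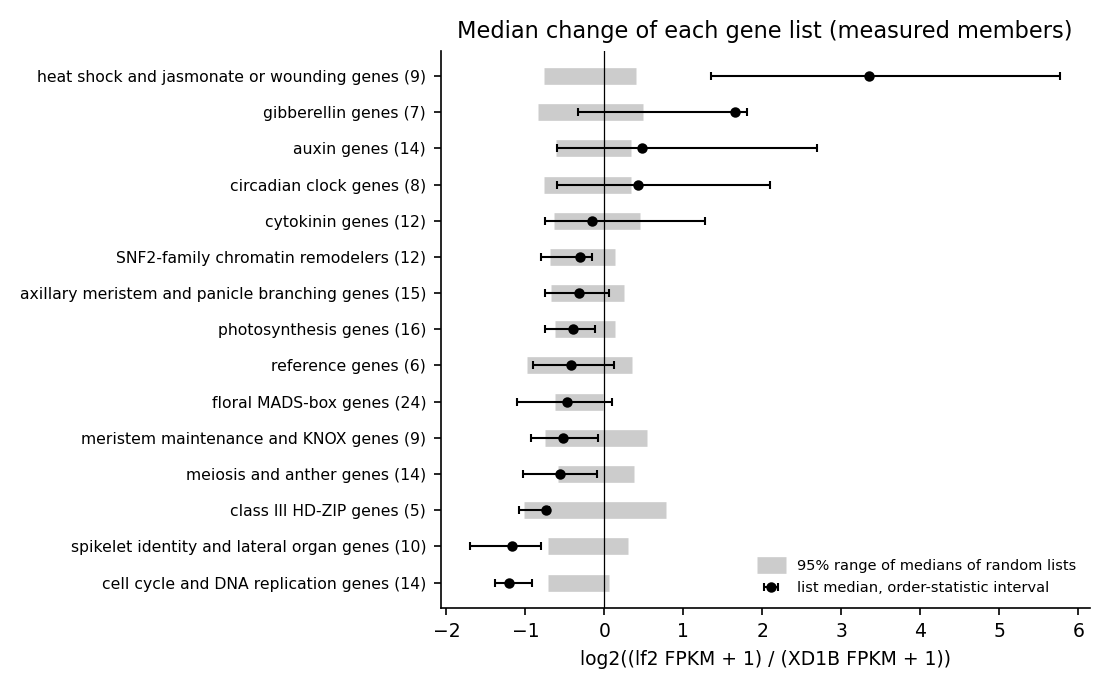
Median log2 ratio of each gene list (horizontal), with its order-statistic interval over members as a line and the 95% range of random-list medians as a grey bar; the number of measured members stands in brackets after each name. The spikelet and cell cycle lists lie left of their grey bars at -1.18 and -1.20, and the heat shock and jasmonate or wounding list lies right of its bar at 3.35.

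Hormone genes were higher or mixed. Of 14 auxin genes, 5 were at least 2-fold higher and 1 at least 2-fold lower, with a median of 0.48 (-0.60 to 2.69) at percentile 98.8. The auxin-conjugating enzyme genes GH3-2 and GH3-8 had ratios of 112 (82.1 to 156) and 6.94 (6.44 to 7.49), and IAA6 a ratio of 8.39 (6.87 to 10.3). With FPKM of at least 5 the auxin list lay at percentile 97.0 and was no longer called. Of 7 gibberellin genes, 4 were at least 2-fold higher, with a median of 1.65 (-0.33 to 1.81) at percentile 99.9. The median over 9 members without a filter was 0.45, at percentile 98.1, and with a pseudocount of 5 it was 0.94. The receptor gene GID1 stood at 58.5 and 186 FPKM, a ratio of 3.18 (3.06 to 3.30), and the synthesis gene GA20ox2 at 3.70 and 15.4, a ratio of 4.17 (3.51 to 4.97).

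Of 12 cytokinin genes, 3 were at least 2-fold higher and 1 at least 2-fold lower, with a median of -0.15 (-0.76 to 1.28) at percentile 67.8 that turns to 0.17 on rescaling to a median ratio of 1. CKX4 and CKX5, which encode cytokinin oxidases, had ratios of 310 (133 to 957) and 5.14 (4.46 to 5.96). CKX2, a cytokinin oxidase gene of the branching list, went the other way, at 1.13 and 0.339 FPKM, a ratio of 0.300 (0.182 to 0.477). The response regulator genes RR6 and RR2 had ratios of 2.60 (2.27 to 2.97) and 0.462 (0.412 to 0.517). The stress and wounding genes were higher in the same library as these hormone genes.

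All 9 measured heat shock and jasmonate or wounding genes were at least 2-fold higher in lf2, with a median of 3.35 (1.35 to 5.77) at percentile 100. TIFY11A, another JAZ gene, stood at 0.0659 and 57.3 FPKM, from 2 fragments in the wild type, a ratio of 868 (240 to 7176). TIFY11D had a ratio of 55.7 (40.9 to 77.8). HSFA2A, a heat shock factor gene, stood at 3.64 and 47.3, a ratio of 13.02 (11.5 to 14.7).

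Circadian clock genes, fixed as markers of collection time, lay at percentile 98.4 with a median of 0.43 (-0.606 to 2.103) over 8 members. Of these, 5 were higher and 3 lower in lf2. Against random lists not matched on expression the list lay at percentile 95.8. Whether the collections differed in time of day was not tested. PRR95 was the 1 member at least 2-fold higher, at 5.17 and 25.5 FPKM, a ratio of 4.93 (4.40 to 5.54). Photosynthesis genes did not stand apart, with a median of -0.40 (-0.75 to -0.11) over 16 members at percentile 32.9. RCA was lower at 7.80 and 2.63 FPKM, CAB1R lower at 49.96 and 21.2, and PORA higher at 50.4 and 109. The 6 reference genes had a median of -0.42 (-0.90 to 0.12) at percentile 60.04, with 0 past the 2-fold rule. ACT1 stood at 353 and 188 FPKM and EIF4A at 313 and 278, and the log2 ratio of EIF4A turns from -0.17 to 0.23 on rescaling to a median ratio of 1.

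**Figure D3:**
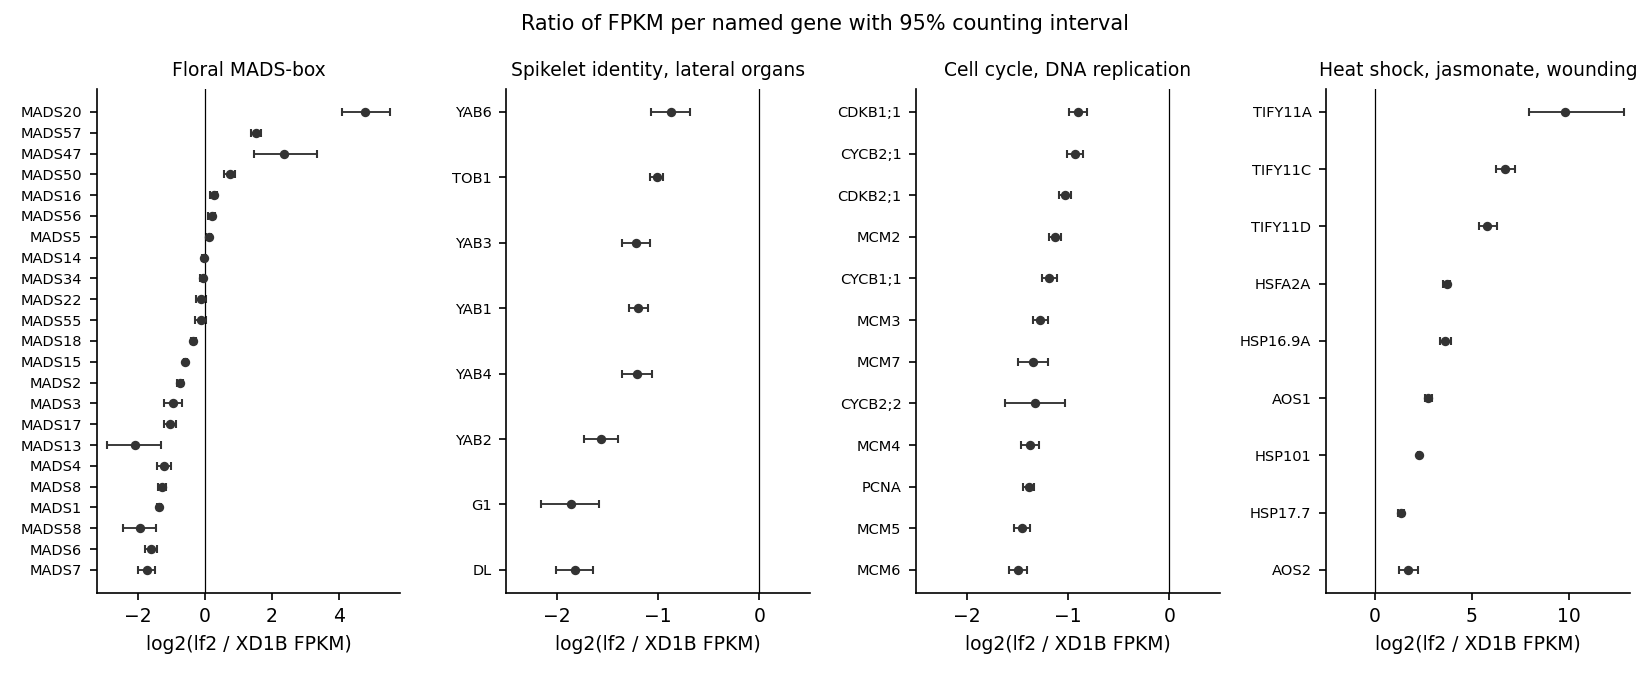
Ratio of FPKM in lf2 to the wild type on a log2 scale for the checked members of 4 lists, with exact 95% counting intervals; horizontal scales differ between panels. MADS7 and DL lie left of 0 in their panels with ratios of 0.298 and 0.282, and TIFY11A lies farthest right with a ratio of 868.

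Outside the lists, the highest log2 ratios among genes with FPKM of at least 5 in either library were at LOC_Os01g24710, at 0.299 and 5129 FPKM, a ratio of 17156 (9037 to 37519), and at LOC_Os08g08970, listed at 0 in the wild type and 2314 in lf2. Against a floor of 3 fragments the latter was at least 11900-fold higher. The lowest were at LOC_Os06g07905, at 16.2 and 0.611 FPKM, a ratio of 0.0377 (0.0237 to 0.0571), and at LOC_Os07g01910, at 7.77 and 0.108, from 2 fragments in lf2, a ratio of 0.0139 (0.00167 to 0.0511).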

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

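Settings for the added lists, restricting lists to checked members and using all members as first fixed were chosen after the data had been seen; the latter pair changed no call, the SNF2-family list having too few checked members (2) for a median; the other settings were planned. No paired analysis was possible because the groups share only 1 replicate number, with 1 library each, and no replicate could be left out. No member stands in more than 1 list (0), so removing shared members moves nothing, and lists by gene description were not run. The number of genes at least 2-fold lower was 2978 with a pseudocount of 0.1, 648 with 5 and 389 after rescaling to a median ratio of 1, and that of genes at least 2-fold higher 2183 with a pseudocount of 5; the pseudocount moves low genes by construction and the rescaling multiplies every lf2 value. Spearman's rho was 0.918 without a filter, where genes at 0 in both libraries enter, and 0.670 at FPKM of at least 5. Rescaling to a median ratio of 1 gave medians of 0.064 for branching, -0.80 for spikelet, -0.35 for class III HD-ZIP, 0.070 for SNF2-family, -0.82 for cell cycle, -0.028 for photosynthesis and 2.05 for gibberellin genes, and changed no call. A sum of 1000000 gave -0.68 for class III HD-ZIP genes. At FPKM of at least 5 the meiosis list became called (-0.92, percentile 0.33, 7 members) and the auxin list lost its call (0.45, percentile 97.0, 10 members), with fewer genes by construction. The circadian list (0.43) lost its call against unmatched random lists, at percentile 95.8; the cause was not tested. The spikelet, cell cycle, gibberellin and heat shock and jasmonate or wounding lists kept their direction and call under all settings run, but the gibberellin median was 0.45 without a filter and 0.94 with a pseudocount of 5. Among named genes, SLR1 (-0.33 to 0.06) and EIF4A changed sign, under rescaling to a median ratio of 1. Of 64 named genes, 58 differed by at least 0.1 from the reported log2 ratio after that rescaling and lay outside their counting interval. The same held for 39 with a pseudocount of 5, 13 with a sum of 1000000 and 1 with a pseudocount of 0.1. Some lay outside as reported, because the log2 ratio carries a pseudocount and the interval does not. CKX4, for example, had a log2 ratio of 4.44 and an interval of the ratio of 133 to 957. The counting intervals cover counting error only and not the choice of scaling. Depth limits genes at 1 to 3 fragments, whose ratios span more than 10-fold.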

Other observations

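The 7 gene lists described next, the genes SALT and LOX1.1 and their alternatives were chosen only after the first results had been seen. So were the tests for green tissue in lf2 and for dilution, and the spread among well expressed genes. The lf2 library held high levels of stress and defence transcripts. Of 10 measured abscisic acid and water deficit genes, 7 were at least 2-fold higher and 0 lower, and NAC6, a stress-induced transcription factor gene, stood at 1.01 FPKM in the wild type and 271 in lf2, a ratio of 269 (210 to 352). RAB16A, a dehydrin gene, had a ratio of 53.5 (32.2 to 96.0). Of 5 WRKY genes checked by position, 4 were at least 2-fold higher, with a median of 4.18 (0.20 to 6.88) at percentile 100. With members without a reference entry 9 of 11 measured were at least 2-fold higher. WRKY71 was listed at 0 in the wild type and 117 FPKM in lf2, at least 601-fold higher against a floor of 3 fragments, and WRKY62 had a ratio of 1287 (440 to 6245). Of 5 checked defence genes, 4 were at least 2-fold higher, and 5 of 6 with members without an entry. The median of the checked genes was 4.05 at percentile 99.9, with an interval of -0.05 to 5.56 that includes 0. PBZ1, a pathogenesis-related protein gene, had a ratio of 77.8 (57.6 to 108), and PAL, the entry enzyme of phenylpropanoid synthesis, stood at 64.7 and 929 FPKM. SALT (LOC_Os01g24710), a lectin gene induced by salt and drought, and LOX1.1, a lipoxygenase gene at 0.140 and 399 FPKM, were among the largest differences.

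Jasmonate genes added after the first results had 5 of 11 members at least 2-fold higher, with TIFY10C at 6.15 and 265 FPKM and the receptor gene COI1A at 84.7 and 82.3. Cellulose synthase and lignin genes were mixed, with 2 of 6 at least 2-fold higher. The lignin genes 4CL3 and CAD2 had ratios of 28.1 (24.1 to 33.0) and 11.9 (8.30 to 17.71), and CESA1 stood at 68.5 and 59.2 FPKM. Of the secondary-wall cellulose synthase genes, CESA4 was lower in lf2, at 5.15 and 2.86 FPKM, a ratio of 0.554 (0.477 to 0.643), and CESA7 and CESA9 stayed under FPKM 1 in both libraries. Of 9 root and ion transporter genes, 4 were at least 2-fold higher, at most at 23.7 FPKM in lf2 (PT8), and 5, among them LSI2 and NAS1 at 0, stood under FPKM 0.1 in both libraries. The median was 2.51 at percentile 99.3 over the 4 measured, most of which passed the filter by their lf2 value alone, and 0.13 over all 9. Of 3 hemoglobin and hypoxia genes 1 was at least 2-fold higher, with a median of 0.11 at percentile 75.3 (2 of 4 with a member without an entry, median 0.91), and PDC2 stood at 219 and 236 FPKM.

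The first pattern weighed is the set of 1831 genes at least 4-fold higher in lf2, against 14 at least 4-fold lower. Green tissue in the lf2 collection is argued against. The upper bound of the photosynthesis list median was 0.24 at its highest over all scalings. Tissue low in photosynthesis transcripts, leaf or other, would escape this test. Heat or wounding during handling may account for part of the first pattern, as the list of such markers lay at percentile 100. So may a jasmonate or wounding response (added list median 0.70) or drying before freezing (2.62). But those lists would also be higher in a mutant with a stress response of its own. Lignifying tissue cannot be told apart, since the 6 members gave a median whose upper bound was 4.40 and whose percentile was 93.5. The members went both ways, with 4CL3 and CAD2 higher and CESA4 lower in lf2. CESA7 and CESA9, left out of the 6 by the filter, stayed under FPKM 1 in both libraries. A difference in collection time was not weighed. The circadian clock list, fixed as its marker, lay at percentile 98.4, with 5 members higher and 3 lower in lf2. A median over members that move apart does not measure a shift in time. The lf2 genotype stays open and untested, because genotype and collection are the same split of 2 libraries.

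The second pattern is the lower level of spikelet organ and cell cycle genes. A general bias by gene length is argued against over 21629 genes above 0 in both libraries. The longest 20% and the shortest 20% of these differed by 0.14 in their median log2 ratio. Recovered lengths are lower bounds, as fragments are, so some genes may be sorted wrongly. The lengths of the spikelet and cell cycle members were not compared. Dilution of panicle RNA by RNA of another tissue cannot be told apart. The intervals of the spikelet and branching medians were 0.05 apart as deposited, which by the test as first written spoke against dilution. They overlapped by 0.11 (a gap of -0.11) after rescaling to a median ratio of 1. This rescaling multiplies every lf2 value alike, so it shifts the lists against each other only through the pseudocount. The overlap thus rests on low genes and does not decide. The demand that every scaling agree was made after the 0.05 had been seen. Among 7469 genes with wild-type FPKM of at least 20, percentiles 1 and 99 of the log2 ratio were -1.50 and 2.09 around a median of -0.50, with 76 genes 2-fold or more below that median and 598 above, a spread that dilution and a broad induction of stress genes would both give, so it does not decide between them. The planned test for more green tissue in 1 collection could not decide. The interval of the photosynthesis list (-0.75 to -0.11, percentile 32.9) crosses the lower edge of its random range, -0.63. Only the later test above argued against green tissue in lf2, and more green tissue in the wild type stays open. A difference of panicle stage cannot be told apart, as the interval of the meiosis list (percentile 4.01) crosses the edge of its random range. That list is also a weak marker here, since C6, EAT1, PTC1 and TDR stayed under FPKM 1 in both libraries. The lf2 genotype stays open.

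The third pattern is that 423 genes with MSU identifiers had FPKM of at least 5 in lf2 and under 0.1 in the wild type, while 0 such genes showed the opposite. Of these, 32.6% had another such gene within 10 loci, against a median of 18.2% and an upper bound of 23.6% in 1000 random sets. Blocks of neighbouring loci that differ between the lines could give such clusters, but 1252 other genes at least 4-fold higher in lf2, all MSU loci with FPKM of at least 5 in either library, were clustered too, by a smaller excess, at 51.3% against a random median of 45.0% and an upper bound of 48.3%. Blocks that are missing or silent in a line leave open why 0 genes were off in lf2. Stress and defence genes described above, among them WRKY71, WRKY62 and TIFY11A, are in the set of 423, so this set overlaps the first pattern. WRKY76, a neighbouring locus of WRKY62, is in it too. How many of the 423 are stress genes was not counted. Tandem copies of stress-response genes and the lf2 genotype were not tested and stay open.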
